A study of Caenorhabditis elegans with 2 samples.

How the data were processed

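ChIP-seq of eGFP-tagged NHR-28 was carried out in L1 larvae of strain OP317, with 2 biological replicates per the labels, which form 1 group. Replicate numbers were taken from the labels. The deposited files are peak lists in narrowPeak format. The file listing deposited with each sample names the genome builds, ce10 and ce11, the type of each list and the files it was made from. The aligner, the peak caller, their versions and the threshold of the final list are not given in the sources used here. The controls' strain and depth are not given there either.

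Per the deposited file listing, the authors made a list of candidate regions, peaks together with background, from each replicate's alignment and a control alignment, and another from both replicates and the control. Each of these lists holds 30000 regions. From the 3 lists of a build they then derived the thresholded list by the irreproducible discovery rate, a measure of how well ranks repeat between replicates. The signal value of each region is the authors' own, deposited in the lists and set relative to a control per the file listing, and it ranks regions within 1 list only. The deposited lists also give a -log10 q value per region, whose column is defined by the narrowPeak format of the deposited file listing. The q values were not used in any test, because 96 of the 159 thresholded peaks share the highest -log10 q value of 2.28 and the others lie between 1.81 and 2.02. No read counts were among the values used, so the depth of each replicate is unknown. Intervals of shares cover counting error over regions only. Differences of depth between the replicates would change how precisely each list ranks its lower regions.

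The analysis used the ce11 lists. Chromosome names and lengths of the reference genome (WBcel235, the same assembly as ce11) were checked against the furthest region on each chromosome, and none reached past a chromosome end. Genes were taken from Ensembl release 115, with 19985 protein-coding genes, and mitochondrial genes without a symbol there were named from RefSeq genes of the same assembly that overlapped them by at least 90% both ways. The ce10 lists served only as an alternative for counts, overlaps, rank correlation and the share on X, and no coordinates were moved between builds.

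A gene was assigned to a region when its start was the nearest protein-coding gene start to the summit and lay within 1 kb. The share near gene starts, the share on X, the gene lists, the noncoding RNA classes and the motifs were each tested with Fisher's exact test, two-sided, on peaks against candidate regions of the pooled list that overlap no thresholded peak, with exact 95% intervals. For the gene lists, the background was the other protein-coding genes with an assigned candidate region. Benjamini-Hochberg adjustment was applied over the 26 gene lists, the 23 motifs, the 2080 6-mers and the 5 noncoding classes, with a threshold of 0.05. Of 322 gene symbols written out in the lists, 318 were found in the annotation. Noncoding genes were counted within 200 bp of a summit. Genes and regions are not independent replicates of the experiment, so these p values compare sets of regions in these 2 replicates.

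Motifs were searched on both strands in windows of 200 bp centred on summits. The background was matched 10 to 1 on GC content, in bins of 2 percentage points, and on lying within 1 kb of a gene start, and 27 of the windows sought were not found. The overlap of the highest regions was tested by permutation with 10000 draws, and rank correlations were given a range from 1000 resamplings of chromosomes. Gene lists, motifs, tests and most alternatives were fixed before the data were examined. The named genes were those assigned to the 15 peaks of highest signal, up to 4 members with the highest signal for each list that passed or held at least 3 assigned genes, nhr-28 and unc-119, and the genes at the 3 peaks with the largest rank gap between replicates. Other names were chosen after their values were seen.

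Alternatives were the ce10 lists, a stricter set of peaks, other overlap criteria and numbers of top regions, distances of 500 bp and 2 kb, other backgrounds, motif windows of 100 and 400 bp, locus windows of 5 and 40 kb, and each replicate's list alone with its 159 highest regions in place of the peaks. Restricting the tests to nuclear regions, searching for a sequence joined from the leading 6-mers and matching the genes of the lists on GC content were added after seeing the data.

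The tests were also tested on simulated data. In 50 draws of 159 random nuclear candidate regions, 2.46% of gene list tests and 3.22% of motif tests had an unadjusted p under 0.05 (exact tests), and 1 draw in each had a list or motif passing after adjustment. With 7 regions at ribosomal protein genes planted, the number found in the data, the list passed in all 50 draws. This does not show how few such genes could be detected. With AGGTCA planted in 10% or 20% of the windows, that motif passed in all 50 draws of each. With the replicate 2 list in random order, the overlap test passed in 0 of 20 draws. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.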

Results

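Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the genomic regions occupied by NHR-28, a nuclear hormone receptor of the nematode Caenorhabditis elegans. Nuclear hormone receptors are transcription factors with a zinc-finger DNA-binding domain. The receptor carried an enhanced green fluorescent protein (eGFP) tag and was expressed from an integrated transgene in strain OP317, whose genotype label also lists a mutation of unc-119, a gene often used as a rescue marker for transgenes. Whole animals of mixed sex were collected at L1, the first larval stage. There was 1 group with 2 biological replicates and no second condition. The questions the design poses are which regions were occupied and whether both replicates show them.

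The deposited values are peak lists, not reads, so the sequencing depth of each replicate is unknown. The list of 30000 candidate regions of replicate 1 had signal values from 8.37 to 917.6 (median 11.3), and that of replicate 2 had values from 6.39 to 800.1 (median 9.01). The list made from both replicates together also held 30000 regions, with signal from 12.5 to 1362. The signal is the authors' value of each region and ranks regions within a list. Coordinates are in ce11.

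The thresholded list held 159 peaks, of which 134 lay on the nuclear chromosomes and 25 on the mitochondrial genome. The nuclear peaks were spread over all 6 nuclear chromosomes, with 22 on I, 24 on II, 23 on III, 13 on IV, 22 on V and 30 on X. The nuclear peaks were 330 bp wide and had signal values up to 125.8, with a median of 58.1. All 159 peaks were the highest-signal regions of the 30000 in the pooled list. A stricter set, with signal above the median of 63.4 and overlap with the 159 highest regions of each replicate, held 68 peaks. It includes mitochondrial peaks, whose lowest signal was 89.8. At any signal, 77 peaks overlapped the highest regions of both replicates, of which 53 were nuclear. The ce10 version of the list held 148 peaks.

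The 22 highest signals were all on the mitochondrial genome, which is 13794 bp long. Of the 15 highest peaks, 14 lay within 1 kb of the start of a mitochondrial protein-coding gene, and together they were assigned to 11 of the 12 such genes. With 12 such genes in 13794 bp, most positions of that genome lie within 1 kb of a start, so neither count shows a preference. Assignment follows the nearest start. The peak from 6066 to 6320, assigned to ND4, has its summit in the coding sequence of COX3. The highest peak spanned positions 12194 to 12852, in the coding sequence of ND5, a subunit of respiratory complex I, with signal 1362. It had rank 1 in replicate 1 and rank 3 in replicate 2. The next one, at 4405 to 5027 in CYTB, the gene of cytochrome b, had signal 1313 and rank 2 in both replicates. The others were assigned to ATP6, ND6, ND4, ND2, ND3, ND1, COX1, ND4L and COX2, genes of the respiratory chain and the ATP synthase. The 25 mitochondrial peaks occupy 19 distinct spans, since some share a span and differ in their summit. Candidate regions covered 71.8% of the mitochondrial genome in the pooled list, against 9.70% of the nuclear genome. The values were 46.0% against 9.54% in replicate 1 and 65.3% against 9.17% in replicate 2.

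Because the rule for named genes selected mitochondrial genes by height, the highest nuclear peaks are also given here, and they were chosen after their values were seen. The highest nuclear peak lay on X from 15607604 to 15607933, in intergenic sequence 200 bp upstream of nipi-3, which encodes a Tribbles-type pseudokinase. Its signal was 125.8, with rank 25 in replicate 1 and rank 29 in replicate 2. The 41 bp centred on its summit, from 15607749 to 15607789, read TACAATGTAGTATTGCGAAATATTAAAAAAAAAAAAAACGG. The next was on V from 1627266 to 1627595, intergenic and 611 bp upstream of the nuclear hormone receptor gene nhr-237, with signal 120.7 and ranks 29 and 23. Its summit sequence from 1627411 to 1627451 was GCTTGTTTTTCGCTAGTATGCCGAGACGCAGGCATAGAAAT. A peak of signal 116.7 on IV from 4749930 to 4750259 lay 145 bp upstream of Y17G9B.5. A peak of signal 103.4 on III from 13643576 to 13643905 lay 171 bp upstream of drr-2, named for its role in the response to dietary restriction.

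Further down the list, cdc-48.1, the gene of a p97-type AAA ATPase, had a peak of signal 88.4 on II from 10563406 to 10563735, 164 bp upstream of its start. The AP-1 factor gene jun-1 had a peak of signal 79.1 on II from 9112798 to 9113127, 194 bp upstream. Several high peaks had no protein-coding gene start within 1 kb. These included one on III at 4237783 to 4238112 with signal 99.4, one on I at 4701088 to 4701417 with signal 97.9, and one on X at 806511 to 806840 with signal 97.1. A peak on III from 8801951 to 8802280, with signal 87.9, lay in an intron of zfp-1.

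**Figure D1:**
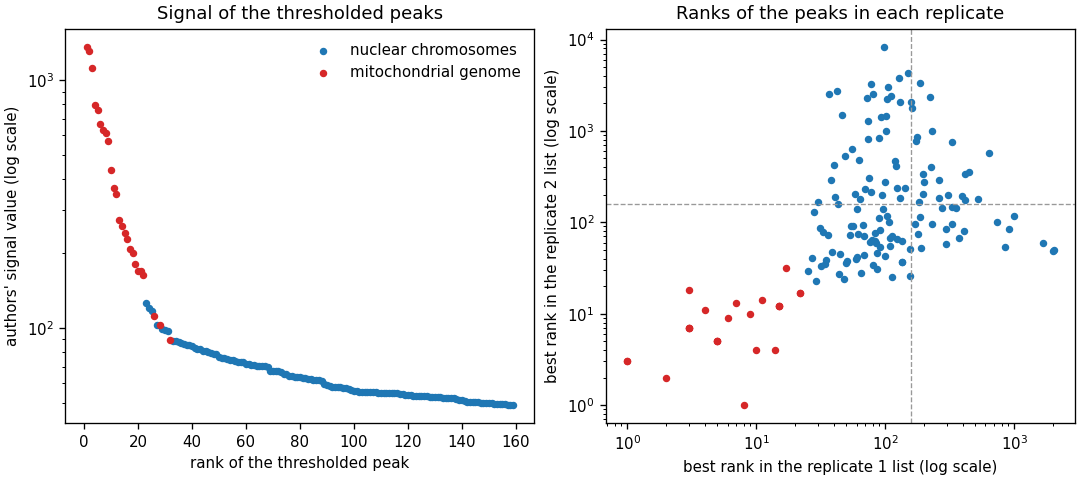
Left, the authors' signal value of each of the 159 thresholded peaks on a log scale against its rank, and right, the best rank of a region overlapping each peak in replicate 1 and in replicate 2 on log scales, with mitochondrial peaks in red, nuclear peaks in blue, dashed lines at rank 159 and 2 peaks missing from the replicate 2 list left out. The 22 highest peaks are mitochondrial, and the nuclear peaks lie on both sides of the dashed lines.

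Genes of the translation machinery were found at the peaks more often than at other candidate regions. Of the 86 genes assigned to a peak, 7 encode ribosomal proteins (8.14%), against 26 of 8184 other genes with a candidate region (0.318%). The odds ratio was 27.7 (exact 95% interval 9.87 to 68.1, Fisher's exact test, adjusted p = 9.2e-07 over 26 lists). In nuclear regions only it was 32.2, and with background genes matched on GC content there it fell to 12.2 (3.404 to 45.3, exact test, adjusted p = 0.0014), both settings chosen after seeing the data. All 7 peaks lay upstream of the gene, between 72 and 402 bp from its start. The highest was that of rpl-3 on III from 3867393 to 3867722, 296 bp upstream, with signal 86.6, rank 39 in replicate 1 and rank 47 in replicate 2. The peak of rps-1 on III from 4475489 to 4475818 lay 264 bp upstream and had signal 71.8 with ranks 85 and 60. The peaks of rpl-12 on IV (13240558 to 13240887, signal 57.1, ranks 407 and 81) and rpl-15 on IV (654805 to 655134, signal 55.2, ranks 74 and 810) ranked far apart in the replicates. The list passed in the 159 highest regions of replicate 1 alone (odds ratio 11.9, exact test, adjusted p = 0.0075) and of replicate 2 alone (odds ratio 18.6, exact test, adjusted p = 0.00044). The genes differed between the replicates, with rpl-3, rps-1, rpl-15 and rpl-35 in replicate 1 and rpl-3, rps-1, rpl-11.2, rpl-12 and rpl-4 in replicate 2, so only rpl-3 and rps-1 were in both. At the peaks, rpl-35 had ranks 77 and 3244 and rpl-11.2 ranks 742 and 102, and these genes and rpl-4 are named after their values were seen. Among peaks with signal above the median, with 38 assigned genes, it did not pass (odds ratio 14.7, exact test, adjusted p = 0.13), nor did any other of the 26 lists.

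Translation factors contributed 3 of the 86 genes against 19 of 8184, an odds ratio of 15.5 (2.88 to 54.2, exact test, adjusted p = 0.017). These were eif-3.C, eef-1A.2 and eif-3.B. The peak of eif-3.C, a subunit gene of translation initiation factor 3, was on I from 9979733 to 9980062, 236 bp upstream of the start, with signal 81.2. That of eef-1A.2, an elongation factor gene, was on X from 7823115 to 7823444, 374 bp upstream, with signal 78.6. The peak of eif-3.B on II from 14794944 to 14795273 had signal 54.2 and ranks 102 and 999. The call was lost in the highest regions of replicate 2 alone (odds ratio 10.3, exact test, adjusted p = 0.25) and held in those of replicate 1 alone (odds ratio 17.1, exact test, adjusted p = 0.0096). Among peaks with signal above the median the odds ratio was higher and the call was lost (22.8, exact test, adjusted p = 0.12). With background genes matched on GC content, a setting chosen after seeing the data, it did not pass (odds ratio 7.44, exact test, adjusted p = 0.18).

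Enzymes of detoxification were the other list that passed. UDP-glucuronosyltransferase and glutathione S-transferase genes made up 4 of the 86 genes against 48 of 8184, an odds ratio of 8.26 (2.11 to 23.4, exact test, adjusted p = 0.017). The peak of gst-5 on II from 10950066 to 10950395 lay 121 bp upstream of the gene, with signal 71.6 and ranks 64 and 178. Those of ugt-58 (II, 9586823 to 9587152, signal 56.9), ugt-13 (V, 4908641 to 4908970, signal 53.8) and ugt-20 (IV, 6083665 to 6083994, signal 49.8) lay 204, 78 and 230 bp upstream. No gene of this list had a region among the 159 highest of replicate 2, and in replicate 1 alone the list did not pass (odds ratio 5.12, exact test, adjusted p = 0.16).

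Nuclear hormone receptor genes, the family of NHR-28 itself, made up 3 of the 86 genes against 139 of 8184. The odds ratio of 2.09 (0.418 to 6.46) did not pass (exact test, adjusted p = 0.61). These were nhr-237, nhr-256 (V, 1743500 to 1743829, 106 bp upstream, signal 64.04) and nhr-87 (IV, 1624422 to 1624751, in an intron 558 bp downstream of the start, signal 53.9). Heat shock proteins and chaperones, with hsp-1 and dnj-9, had 2 genes (odds ratio 7.19, exact test, adjusted p = 0.23). That list depended on the setting. It passed in the highest regions of replicate 1 alone (4 genes, odds ratio 16.6, 4.12 to 49.7, exact test, adjusted p = 0.0047) and with all genes starting within 1 kb of a summit (6 genes, odds ratio 15.6, 5.22 to 38.7, exact test, adjusted p = 8.5e-05). In replicate 2 alone it did not (odds ratio 3.94, exact test, adjusted p = 0.86). The 6 genes included hsp-90, an intron of which holds the peak assigned to C47E8.4 (V, 14685633 to 14685962, signal 83.4). The list was set by symbol, so chaperone genes under other symbols are not counted. Chemoreceptor genes had 1 gene, srh-16, against 526 others (odds ratio 0.171, exact test, adjusted p = 0.23). Histones (his-37), the respiratory chain and ATP synthase (cox-5A), fatty acid and lipid metabolism (acs-6) and collagens (col-63) had 1 gene each, named like hsp-1 and dnj-9 after their values were seen, with adjusted p from 0.55 to 1.0 in the exact test. The respiratory chain list was set from symbols of nuclear genes, so it holds none of the mitochondrial genes at the highest peaks, and it lacks ndua-7, a complex I gene with a peak on II from 13494828 to 13495157. None of the assigned genes belonged to the lists of homeobox factors, of bHLH, bZIP, forkhead, GATA and SOX factors, of V-ATPase subunits, vitellogenins, cytochrome P450s, molting and hedgehog-related genes, innate immunity, or neuropeptides and insulins. The same held for the marker lists of intestine, body wall muscle, pharynx, hypodermis and seam, neurons, germline, excretory system and glia. The adjusted p of each of these 16 lists was 1.0 in the exact test. Of the 86 assigned genes, 75 are nuclear. A short list, such as vitellogenins (6 genes) or glia (16), would hold few or none of them by chance. A count of 0 in such a list therefore cannot show that its genes are avoided. The lists were set by gene symbol, and that of bHLH, bZIP, forkhead, GATA and SOX factors lacks jun-1, a bZIP gene with an assigned peak. Members of that list with a peak beyond 1 kb of their start are not counted either. These include skn-1, with peaks in its introns, zip-2, with one in its 3' UTR, and sbp-1, with one 2444 bp upstream.

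Among genes of noncoding RNA, those of small nuclear RNA were found near nuclear peaks. Over all 159 peaks, 14 had a tRNA gene within 200 bp of the summit, 7 an rRNA gene and 4 a small nuclear RNA gene, against 122, 0 and 21 of 29819 other regions. All 25 mitochondrial regions of the pooled list were peaks, so the other regions are nuclear only and these counts do not compare like with like. The nuclear peaks were then tested alone, a setting chosen after seeing the data. Of the 134 nuclear peaks, 4 (2.99%) had a small nuclear RNA gene within 200 bp of the summit, against 21 of 29819 other candidate regions (0.0704%). The odds ratio was 43.6 (10.7 to 131.8, exact test, adjusted p = 2.3e-05 over 5 classes). The class also passed in the highest nuclear regions of replicate 1 alone (3 regions, odds ratio 23.9, exact test, adjusted p = 0.0019) and of replicate 2 alone (5 regions, odds ratio 81.8, exact test, adjusted p = 9.5e-08). The genes at the peaks were sls-2.1, sls-2.2 and sls-2.4, named here after their values were seen. They encode spliced leader RNAs of the SL2 type, which are joined to messages from downstream genes of operons. The peaks lay on II from 5844662 to 5844991 (signal 88.7), on II from 5543532 to 5543861 (signal 80.5) and on I from 4171950 to 4172279 (signal 74.8). A further peak (4172149 to 4172478, signal 51.2) overlaps the last and is also near sls-2.4. Both have the same best ranks in the replicates, 134 and 37, so the test counts this place more than once. All 4 peaks were at these 3 sls-2 genes, so the result concerns them rather than the whole class. Transfer RNA genes lay near 2 of the nuclear peaks (odds ratio 3.69, exact test, adjusted p = 0.27). No nuclear peak had a snoRNA, miRNA or rRNA gene within 200 bp, with adjusted p = 1.0 for each class in the exact test.

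**Figure D2:**
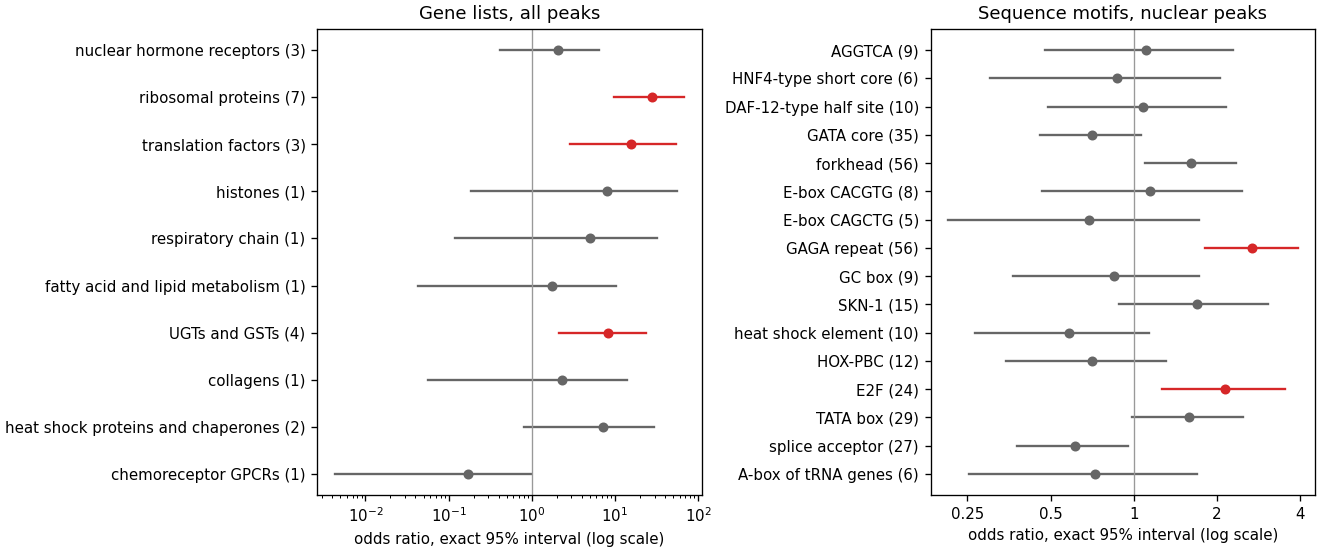
Odds ratios (points) with exact 95% intervals (lines) on log scales, left for each gene list with at least 1 assigned gene and right for each motif found in at least 5 nuclear peaks, with the number of genes or peaks in brackets and red for an adjusted p below 0.05. The intervals of ribosomal proteins (9.87 to 68.1) and of the GAGA repeat (1.81 to 3.92) lie above 1, and that of AGGTCA (0.478 to 2.29) spans 1.

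The peaks lay close to gene starts. Of the 159 peaks, 100 (62.9%, exact 95% interval 54.9 to 70.4) had their summit within 1 kb of the start of a protein-coding gene, against 10645 of 29819 other candidate regions (35.7%). The odds ratio was 3.05 (2.19 to 4.29, Fisher's exact test, two-sided, p = 5.2e-12). The other regions are all nuclear, so the nuclear peaks are the like comparison. Of these, 76 of 134 (56.7%, 47.9 to 65.2) did so, an odds ratio of 2.36 (1.65 to 3.38, exact test, p = 8.0e-07). Upstream of the gene start lay 67 of these 76, at a median of 231 bp, and 9 lay downstream. By annotation, 103 nuclear summits (76.9%) were intergenic, 23 were in introns, 5 in 5' UTRs, 2 in 3' UTRs and 1 in a coding exon, that of abhd-5.2 on V from 4844653 to 4844982. Of 3000 other nuclear candidate regions drawn at random, 46.2% were intergenic, 38.1% intronic and 8.93% in coding exons.

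Chromosome X held 30 of the 134 nuclear peaks (22.4%, 15.6 to 30.4), against 18.1% of the other candidate regions. The odds ratio of 1.30 (0.836 to 1.97) did not pass (Fisher's exact test, two-sided, p = 0.22). Among the 54 nuclear peaks with signal above the median of the list, 16 were on X (29.6%, 17.98 to 43.6), an odds ratio of 1.90 (exact test, p = 0.034) whose interval of 0.988 to 3.49 includes 1.

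GAGAGA repeats were the most enriched of the 23 motifs at the peaks. They were found in 57 of 159 windows of 200 bp (35.8%) against 290 of 1563 matched windows (18.6%), an odds ratio of 2.45 (1.70 to 3.52, exact test, adjusted p = 2.9e-05). In the nuclear peaks the share was 56 of 134 (41.8%) against 21.2%, an odds ratio of 2.67 (1.81 to 3.92, exact test, adjusted p = 1.0e-05). The motif passed in the highest regions of each replicate alone, with odds ratios of 2.25 in replicate 1 and 2.64 in replicate 2. The E2F-type sequence TTSSCGC was found in 15.1% against 8.32% (odds ratio 1.96, exact test, adjusted p = 0.046), and it did not pass in either replicate alone. Forkhead-type sequences (TRTTTRY) were found in 45.9% of all peak windows against 33.6% (odds ratio 1.68, exact test, adjusted p = 0.017), and in the nuclear peaks they did not pass (odds ratio 1.61, exact test, adjusted p = 0.087), nor in the highest regions of replicate 2 alone (odds ratio 1.51, exact test, adjusted p = 0.17). The splice acceptor sequence TTTCAG was rarer at peaks, in 18.9% against 31.1% (odds ratio 0.516, exact test, adjusted p = 0.012), and in the nuclear peaks this difference did not pass either (odds ratio 0.611, exact test, adjusted p = 0.15), nor did it in replicate 2 alone (odds ratio 0.641, exact test, adjusted p = 0.21).

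Sequences bound by nuclear receptors were not detectably more frequent at the peaks. The hexamer AGGTCA was found in 9 of 159 windows (5.66%) against 4.80% (odds ratio 1.19, 0.513 to 2.45, exact test, adjusted p = 1.0). AGTCCA, part of the HNF4-type site, was found in 4.40% against 4.67% (odds ratio 0.940, 0.359 to 2.09, exact test, adjusted p = 1.0). The longer HNF4-type sequence AAAGTCCA occurred in 1 window, TCAAGGTCA in none, and the DAF-12-type AGTGCA in 6.92% against 7.10%. None of the other motifs passed with matched windows of 200 bp, which were those of GATA factors, E-boxes, the GC box, KLF, SKN-1, heat shock factor, HOX-PBC, CRE, PAR bZIP, the TATA box, and the A-box and B-box of tRNA genes. The TATA box passed with windows of 400 bp (odds ratio 1.55, exact test, adjusted p = 0.049). The heat shock element was rarer at peaks against an unmatched background (odds ratio 0.446, exact test, adjusted p = 0.035).

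Of 2080 6-mers tested, 31 were more and 6 less frequent in all peaks than in matched regions after adjustment. In the nuclear peaks 31 were more and 3 less frequent. The leading ones were GACGCA (39 windows, 29.1% against 9.67%, exact test, adjusted p = 6.6e-06), AGAGAC (34.3% against 13.3%, exact test, adjusted p = 7.8e-06), ACGCAG (29.1% against 10.7%, exact test, adjusted p = 2.9e-05) and CGTCTC (31.3% against 12.9%, exact test, adjusted p = 0.00012).

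The replicates placed many of their highest regions at the same positions. Of the 159 highest regions of replicate 1, 74 (46.5%, 38.6 to 54.6) overlapped one of the 159 highest of replicate 2. Regions drawn at random from the replicate 2 list gave a mean of 0.9002 and at most 8 in 10000 draws (one-sided permutation p = 0.0001, the smallest these draws can give). Among nuclear regions, 52 of 134 (38.8%) were shared against 0.610 by chance. Among the 1000 highest regions of each replicate, the shared part fell to 195 (19.5%) against 23.8 by chance.

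Ranks went together only weakly over all matched regions and over those at nuclear peaks. Across 10739 regions of replicate 1 that overlapped a region of replicate 2 (35.8% of 30000), Spearman's rho was 0.139, with a range of 0.122 to 0.165 when chromosomes were resampled. For the 5000 highest regions of replicate 1 it was 0.237, over 2451 matched regions. For regions at thresholded peaks it was 0.449 (0.111 to 0.769), and without the mitochondrial genome 0.198 (0.0855 to 0.324). These are correlations across regions, which are not independent replicates. The peaks are the highest regions of a list made from both replicates. That choice narrows the range of ranks and can change rho, so the values at peaks alone do not measure how well the replicates agree.

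Of the 134 nuclear peaks, 53 overlapped a region among the 159 highest of both replicates, 93 one of replicate 1 and 73 one of replicate 2, and 21 neither. The largest rank gaps were at a mitochondrial peak (11213 to 11672, assigned to ND5, with its summit in the coding sequence of ND3) and at ugt-58. Neither had an overlapping region in the replicate 2 list, against ranks 14 and 47 in replicate 1. A mitochondrial peak overlapping the first, from 11174 to 11672, had ranks 14 and 4, so that gap depends on where the spans end. The next largest gap was at srh-16, a chemoreceptor gene, on V from 12291704 to 12292033, in the 5' UTR, with rank 98 in replicate 1 and 8304 in replicate 2.

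The nhr-28 gene itself, on X from 16354976 to 16359650, had no thresholded peak. Within 20 kb of it lay 1 pooled candidate region, with rank 17376. That is 0.224 regions per 10 kb (exact Poisson 95% interval 0.00567 to 1.25), against a median of 2.70 over 19985 protein-coding genes. At this window 1.58% of genes had as few or fewer, and the share was 12.7% with a window of 5 kb and 13.3% with 40 kb. Replicate 1 had 1 region there and replicate 2 had none. The gene lay in a stretch of 61.6 kb without a candidate summit in the pooled list, of 51.5 kb in replicate 1 and of 63.1 kb in replicate 2. The median spacing between summits was 1844 bp in the pooled list. Around unc-119, on III from 10902641 to 10908935, there were 19 pooled candidate regions within 20 kb, or 4.10 per 10 kb (2.47 to 6.41), more than at 83.7% of genes. The highest had rank 3157 and none was a thresholded peak. Within 5 kb of unc-119 the density was 6.75 per 10 kb.

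**Figure D3:**
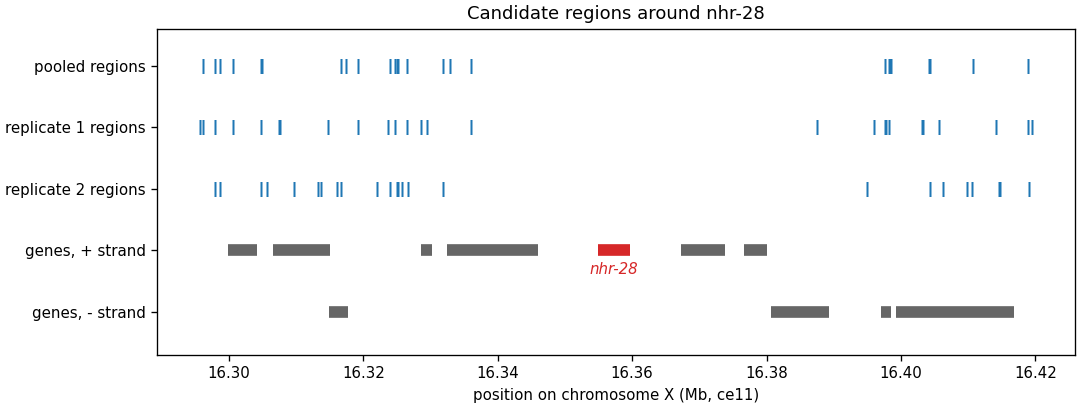
Candidate regions of the pooled list and of each replicate (blue) and protein-coding genes by strand (grey, nhr-28 in red) along chromosome X in Mb, ce11, within 60 kb of nhr-28. None of the 3 lists has a region over nhr-28, and the summits nearest to it in replicate 1 are at 16336037 and 16387541.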

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

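Nuclear regions only and GC-matched background genes were chosen after seeing the data; the other alternatives were planned. The share of peaks near gene starts and the overlap of the replicates' highest regions stayed above their backgrounds with every alternative run. The strict set kept 68 peaks, mitochondrial ones included. Rank correlation rose to 0.178 with 50% reciprocal overlap and to 0.237 for the 5000 highest regions of replicate 1. With peaks above the median signal, the share on X rose to 29.6% and passed its test narrowly, with an odds ratio interval (0.988 to 3.49) that includes 1, and the number of gene lists passing fell from 3 to 0 with fewer genes tested, although the odds ratio of translation factors rose from 15.5 to 22.8. On 1 replicate alone, the number of lists passing ranged from 1, ribosomal proteins in replicate 2, to 3 in replicate 1, where heat shock proteins and chaperones (odds ratio 16.6) passed in place of UDP-glucuronosyltransferases and glutathione S-transferases. Heat shock proteins and chaperones also passed as a list beside the 3 others with all genes starting within 1 kb (15.6). With GC-matched background genes 2 lists passed, without translation factors. The odds ratio of UDP-glucuronosyltransferases and glutathione S-transferases was 0 in replicate 2 alone and 5.12 in replicate 1 alone, without a pass, and stayed above 1 in every other setting. That of nuclear hormone receptor genes fell below 1 with a distance of 500 bp (0.767) and stayed above 1 in every other setting, without a pass in any. It was 3.09 with 2 kb and 4.24 with GC-matched background genes. The number of motifs passing fell from 4 to 2 with windows of 100 bp and with nuclear regions only, to 3 with peaks above the median signal, and ranged from 1 to 3 on 1 replicate alone. It rose to 5 with windows of 400 bp, where the TATA box was added (odds ratio 1.55), which fell to 0.906 against an unmatched background. With that background 4 passed, with the heat shock element, rarer at peaks (0.446), in place of the forkhead sequence (1.39). The 5 nuclear receptor sequences passed in no setting, and the odds ratio of each lay above 1 in some settings and below 1 in others. AGGTCA had 0.251 with windows of 100 bp, 0.880 with 400 bp, 0.999 to 1.20 on 1 replicate alone, 1.46 against an unmatched background and 1.82 with peaks above the median signal. AAAGTCCA, in at most 1 window of any setting, had 3.33 with 100 bp, 2.51 above the median signal, 0.493 with 400 bp, 0.848 unmatched, 0 in nuclear regions and 0.898 to 1.11 on 1 replicate alone. AGTCCA had 1.11 with 100 bp, 0.767 with 400 bp, 1.21 unmatched, 1.07 above the median signal, 0.872 in nuclear regions and 0.646 to 0.782 on 1 replicate alone. AGTGCA had 0.680 with 100 bp, 1.34 with 400 bp, 1.26 unmatched, 1.22 above the median signal, 1.08 in nuclear regions and 1.399 to 1.411 on 1 replicate alone. TCAAGGTCA had 2.49 with 400 bp, with 1 window, no finite value in replicate 2 alone, where no background window held it, and 0 in the others. Around nhr-28, the density was 0 regions per 10 kb within 5 kb, 1.54 within 40 kb, and 0 to 0.224 on 1 replicate alone. Around unc-119 it was 6.75 within 5 kb and 3.67 to 4.10 on 1 replicate alone. The causes were not tested. Alternatives were run value by value for 5 lists and 11 motifs, which were those passing in any setting and those of nuclear receptors. Of 45 list values and 76 motif values, 35 and 46 kept their direction and side of the threshold, 6 and 10 lost their call with the same direction, 2 and 2 gained one, and 2 and 18 changed direction. The depth of the replicates is unknown, and 159 peaks limit the precision of every share.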

Other observations

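The search for GAGACGCAG, the tests on nuclear regions alone or with GC-matched background genes, and the tests of mitochondrial DNA abundance, of peaks of 1 replicate, of chance spacing and of extra copies were chosen after the results were seen. Further nuclear receptor genes were the nearest to peaks beyond the 1 kb limit. These were nhr-84 (V, 15880738 to 15881067, 1295 bp upstream, signal 76.002), nhr-61 (II, 14822488 to 14822817, 4110 bp upstream, signal 55.8), nhr-19 (II, 9603382 to 9603711, in its intron, signal 50.6) and nhr-1 (X, 17505785 to 17506114, 8113 bp upstream, signal 49.5). Introns of skn-1, the gene of a factor of the oxidative stress response, held 2 peaks (IV, 5655981 to 5656310, signal 55.1, and 5657061 to 5657390, signal 49.8). A peak also lay 80 bp upstream of wdr-23, which encodes a repressor of SKN-1 (I, 7595531 to 7595860, signal 58.1). Of the 18 annotated sls-2 genes, 3 had a peak within 200 bp. No candidate region, peak or other, lay that close to any of the 12 sls-1 genes. The same held for nuclear rRNA genes, with 0 of 134 nuclear peaks and 0 of 29819 other regions that close. Where no candidate region is listed at all, the lists cannot tell a lack of signal from sequence where no region could be called. The difference between the sls-2 and sls-1 genes was not tested and is not evidence of a preference.

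Of the leading 6-mers of the nuclear peaks, GACGCA, ACGCAG, CGTCTC and AGACGC overlap, with both strands read, to form GAGACGCAG. AGAGAC and GAGAGA are not contained in it, but AGAGAC overlaps its start, and CGCAGA, another enriched 6-mer, overlaps its end. The enrichments are thus not separate signals, and how far that of GAGAGA comes from the same places was not tested. GAGACGCAG was found in 25 of 134 nuclear peak windows (18.7%) against 4.49% of matched windows, an odds ratio of 4.87 (2.80 to 8.26). That value is not independent of the 6-mer search. In nuclear candidate regions ranked after the thresholded peaks, down to rank 1000, the sequence was found in 42 of 837 windows (5.02%) against 138 of 8218 matched windows ranked lower (1.68%). The odds ratio there was 3.09 (2.12 to 4.44, exact test, p = 1.1e-08). Among the highest nuclear regions of each replicate the odds ratios were 5.33 in replicate 1 and 4.40 in replicate 2. These are not independent of the search either, since 93 and 73 of the 134 nuclear peaks overlap those regions. The peaks with the sequence included those of nhr-237, drr-2, nhr-256, sti-1 and ugt-58. With 1 mismatch allowed, the only other form of the search tried, the odds ratios were 3.88 in the nuclear peaks and 2.16 in the regions down to rank 1000. Which protein binds it was not tested.

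The highest signals were on the mitochondrial genome. Low GC content alone is not enough for such signals. Of 4675 nuclear candidate regions with GC content at or below the 24.5% median of the mitochondrial peaks, only 0.0428% (0.00518 to 0.154) overlapped a thresholded peak. Candidate regions covered at least 46.0% of the mitochondrial genome in each of the 3 lists instead of a few sites. This coverage was seen before the test was set, and the signal is set relative to a control. It therefore cannot decide whether the many copies of mitochondrial DNA per cell contribute. No biological explanation was tested, including binding of NHR-28 to mitochondrial DNA, and the control's own mitochondrial signal was not used here.

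Ribosomal protein genes stood out among the peaks. With background genes matched on GC content, the odds ratio of ribosomal protein genes was 12.2 (3.404 to 45.3) in nuclear regions, down from 32.2 without matching, so GC content does not account for the whole excess. The list passed in each replicate alone, with the higher adjusted p at 0.0075 (exact test), which argues against 1 replicate as the source of the excess, although only rpl-3 and rps-1 were in both. It stays open whether the signal is specific to NHR-28 or may occur at active promoters for any tagged factor. AGGTCA was not detectably enriched in the nuclear peaks, with an odds ratio of 1.11 (0.478 to 2.29), and no profile of another factor or of untagged animals was analysed here, so these cannot be told apart and no biological explanation was tested.

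The tagged gene sat in a long stretch without candidate regions in both replicates. Stretches as long were rare, with at most 0.896% of protein-coding genes in one in either replicate list (1.86% in the pooled list). That test was set after the stretch was seen, so it cannot decide on chance spacing. In the planned windows, 1.58% of genes had as few regions or fewer within 20 kb, 12.7% within 5 kb and 13.3% within 40 kb. The stretch's share of soft-masked bases, 36.1%, was at percentile 61.9 of stretches of its length. The stretch is thus not unusually rich in masked repeats, but soft-masking does not measure where reads can be placed, so unmappable sequence stays open. Whether extra copies of the locus in the transgenic strain are involved stays open. No summit lay closer than 18.9 kb to the gene on either side in a replicate list. That distance is the edge of the stretch itself and was known before the test was set, so it is no support. Extra copies in the ChIP sample can raise read density, which is the opposite of an empty stretch, while copies in the control could lower the signal. The peak caller is not given in the sources used here, so how it treats stretches of unusual read density is unknown. The strain of the control is not given in the labels, so extra copies cannot be told apart from other properties of the locus. An earlier form of this test asked for few regions at unc-119 as well and was not met, since 83.7% of genes had fewer regions than unc-119. It was replaced after that value was seen, because the labels do not say which form of unc-119 the transgene carries, and no biological explanation was tested.

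By length, the stretch that holds nhr-28 ranked 18 of 29993 in the pooled list, 11 in replicate 1 and 4 in replicate 2. Longer stretches without candidate summits included those on V from 2341338 to 2566216 (224.9 kb in the pooled list, 220.1 kb in replicate 1, 234.2 kb in replicate 2) and on V from 8799530 to 8900190 (100.7, 100.8 and 100.6 kb). The second longest of the pooled list was on I from 12256366 to 12417211 (160.8 kb).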
